A study of Homo sapiens with 12 samples.

How the data were processed

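RNA from endometrial stromal cells was measured on 12 expression arrays, from 2 donors at 6 times (0, 2, 12, 24, 36 and 48 h). The table holds 12625 probe sets in 12 columns, 1 per array. Each deposited value is a linear ratio of a probe set's signal to that probe set's median over the 12 columns. This was checked on the values: the row median was 1 within 0.001 in 12624 rows and differed in 1. How the signals were made and scaled between arrays before that step is not stated. The column medians ran from 0.971 to 1.09 and the values from 0.000581 to 705.4. Ratios carry no absolute level, so a dim probe set cannot be told from a bright one, and the number of arrays limits the precision.

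The columns labelled 0 h of donor 1 and 2 h of donor 2 hold the same value in all 12625 rows. At least 1 of the labels therefore belongs to another array, and the values do not show which. The planned comparisons were fitted without both columns, on the 10 arrays left, with 1 array at 0 h (donor 2), 1 at 2 h (donor 1) and 2 at each later time. The fit planned before the data were examined used all 12 columns and is given as an alternative. Gene symbols came from the probe table and were updated through Entrez gene IDs to the RefSeq annotation of GRCh38.p14, which matched 10918 probe sets and left 9 with the symbol of the probe table. After 67 control probe sets and 16 for X-inactivation or Y-linked genes were left out, 12542 probe sets were tested. Of these, 10927 carried 1 symbol, 545 carried several and 1070 were not listed. They gave 8210 genes, 1928 of them with more than 1 probe set.

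Log2 ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with time as a factor and 1 estimate of the spread shared by all times. The fit had 4 residual and 3.59 prior degrees of freedom, and the median residual SD was 0.718 on the log2 scale. A lone array at 0 h or 2 h is assumed to vary like the other groups. Comparisons were an F over the 5 contrasts with 0 h, each later time against 0 h, 12 to 48 h against 0 h, 2 h against 12 to 48 h, and 48 h against 12 h. Probe sets with a Benjamini-Hochberg adjusted p under 0.05 passed. Errors given after ± are standard errors of the fit unless named otherwise. The donors come from the labels. The correlations between the donors' differences at the later times ran from -0.087 to 0.098 with a mean of -0.025, so the values do not show the pairing. A fit with the donor as a block was run beside each comparison.

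A further comparison, 24 to 48 h against 0 or 2 h, was devised after the planned comparisons had been run. Among those, only 12 h against 0 h and 48 h against 12 h had given calls at the level of probe sets. The identical column enters it once, since both of its labels lie in the 0 or 2 h arm, and the 12 h arrays stay out, which gives 3 arrays against 6. This fit has 2 groups and its own estimate of the spread. A comparison of 36 h with 24 h was also added after the data were examined.

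Named genes follow a rule written before the data were examined, applied to probe sets with exactly 1 symbol. For 2 h against 0 h and 12 to 48 h against 0 h it takes up to 12 genes per direction with the largest change among those that passed with 1 direction in both donors. For the other comparisons it takes up to 5. In comparisons with 0 h or 2 h, the later arrays of both donors were set against the same early array. For 2 h against 0 h the condition on donors was thus met by every probe set. Where fewer than 3 passed, the 3 largest changes are given as values that did not pass. From each list it takes up to 4 passing members, or else up to 2 with the smallest p. A set of 16 genes was always followed, as the mean of a gene's probe sets. The added comparison of 24 to 48 h uses the rule with up to 12 genes.

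Gene lists were written before the data were examined: 32 lists of 833 genes, 724 of them measured. Each was tested with limma's camera, two-sided, with a preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry, also chosen before the data were examined, were run beside it. A gene with several probe sets entered the lists as their mean, since the planned choice of the brightest probe set needs levels; that choice by mean ratio is an alternative. The lists cover decidualization markers, immediate cAMP and CREB targets, protein kinase A components, DNA replication, mitosis, cell cycle inhibitors, actin and contractile genes, SRF and YAP targets, matrix, proteases, the insulin-like growth factor system and steroid genes. Others cover cholesterol synthesis, cytokines, interferon-stimulated genes, oxidative stress, metallothioneins, the TGF-beta and WNT pathways, vascular factors, endoplasmic reticulum stress, heat shock, glycolysis, oxidative phosphorylation, ribosomal proteins, housekeeping genes and neuronal genes. The last 5 hold markers of epithelium, leukocytes, endothelium, pericytes and stromal fibroblasts.

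Alternatives chosen before the data were examined were quantile normalization, a pseudocount of 0.645 (the 20th percentile of all values) before log2, an intensity trend with a robust prior, the donor as a replicate block, only the arrays compared, and each array left out in turn. The fit on all 12 columns, as first designed, became an alternative once the identical columns were found. Added after the data were examined were the identical column as a 0 h or as a 2 h array, the arrays with high hybridization controls left out (7 arrays remain), and those controls as a covariate. Array weights, centred medians, 24 to 48 h in place of 12 to 48 h, and probe sets averaged per gene were also added. The planned floor, filter on dim probe sets and count of 2-fold changes in both donors were not run, because ratios have no level and only 1 donor keeps a 0 h array.

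The tests were tested on simulated data with the 12542 probe sets and the design. Of 100 probe sets changed by 2 on the log2 scale, 0% passed for 12 h against 0 h, 2% for 12 to 48 h against 0 h, 1% for 48 h against 12 h and 55% for 24 to 48 h against 0 or 2 h. At a change of 4 the shares were 18%, 46%, 65% and 97%. False calls numbered 0 to 5 per run. A simulated list of 30 genes shifted by 1 gave a camera p of 1.84e-09, and 2.01% of the unshifted lists had a p under 0.05. The simulated genes were drawn independently, each with 1 spread for all arrays. Members of real lists can be correlated and the 12 h arrays had a larger spread, so these rates may not hold for the data.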

Results

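Gene expression was measured in human endometrial stromal cells, the connective tissue cells of the uterine lining, which cyclic AMP (cAMP) turns into decidual cells. The title of the series names cAMP as the inducer. The labels give 6 times (0, 2, 12, 24, 36 and 48 h) and 2 donors, with 1 array per donor and time. They give no dose and name no array kept for 2 to 48 h without cAMP, so each comparison is between times. All values are ratios to a probe set's own median over the 12 arrays, compared here as log2 differences. The 0 h array of donor 1 and the 2 h array of donor 2 hold identical values throughout, and neither entered the planned comparisons. That left 1 array at 0 h, 1 at 2 h and 2 at each later time.

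Both arrays at 12 h differed from the rest in their control probe sets, as did the 48 h array of donor 2 and the identical column. The 9 hybridization control probe sets, which detect transcripts added during preparation, had median log2 ratios of 1.68 and 3.60 at 12 h, 1.38 on the 48 h array of donor 2 and 1.36 in the identical column. On the other 7 arrays these medians ran from -0.92 to 0.09. The GAPDH probe set at the 5′ end of the transcript stood against the one at the 3′ end at -4.17 and -1.06 on the log2 scale at 12 h, -3.84 on the 48 h array of donor 2 and -2.13 in the identical column. The SD of all log2 ratios was 1.47 and 1.99 on the 12 h arrays, 1.03 on the 48 h array of donor 2 and 0.69 to 0.88 on the other 7.

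**Figure D1:**
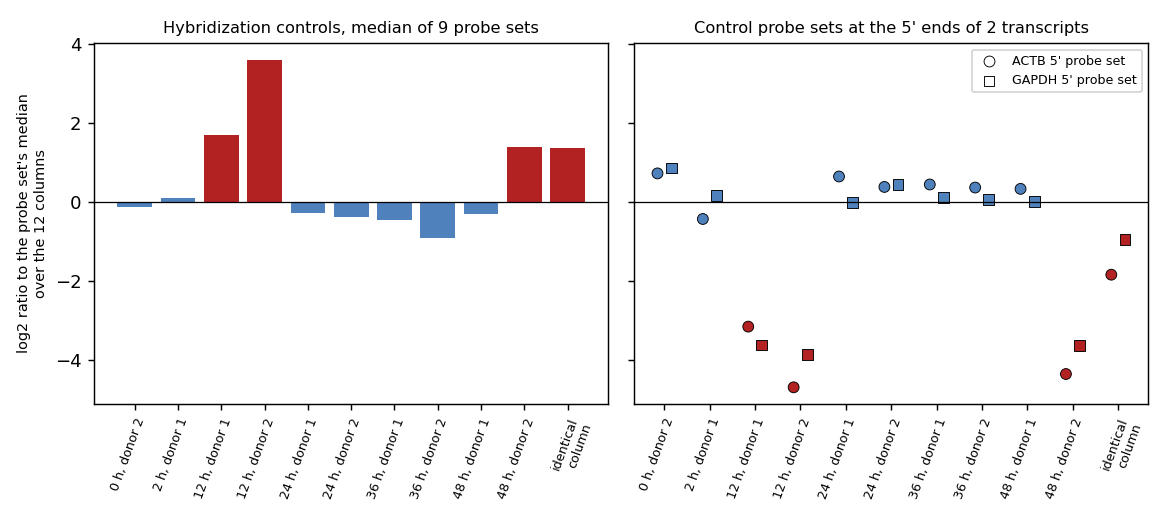
Left, the median log2 ratio of 9 hybridization control probe sets per array (bars); right, log2 ratios of the control probe sets at the 5′ ends of ACTB (circles) and GAPDH (squares). Red marks arrays whose hybridization controls exceed 1 on the log2 scale: both 12 h arrays (1.68 and 3.60), the 48 h array of donor 2 (1.38) and the identical column (1.36).

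Which genes respond first was asked by comparing 2 h with 0 h. NR4A1, an orphan nuclear receptor and an immediate early gene, stood 5.63 ± 1.0 higher at 2 h on the log2 scale by 1 of its 3 probe sets, and the others at 3.98 and -0.53. Its mean over 3 probe sets was 3.03 ± 0.77, and NR4A3, a gene of the same family, stood at 3.07 ± 0.79. CHI3L1, a secreted chitinase-like protein, was at 6.64 ± 3.13 and PSPHP1, a pseudogene, at 5.64 ± 3.01. Lower values were those of the beta-globin gene HBB at -7.38 ± 1.31, FAM13C at -4.79 ± 2.06 and RAPGEF3, a cAMP-activated exchange factor, at -4.61 ± 0.68 (its other probe set -0.85). HBB was high on the single 0 h array alone, at 5.78 against -1.28 to 0.97 in all other columns. No probe set passed (0 of 12542 in limma, with 412 at an unadjusted p under 0.05), and 1 array stood against 1 from the other donor, so time and donor are separated only in the blocked fit, through the later arrays of both donors.

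The other genes always followed stood, at 2 h against 0 h, at -1.71 ± 1.80 (PRL), -2.77 ± 1.0 (IGFBP1), -1.09 ± 0.71 (FOXO1), -0.79 ± 0.67 (CREM), 0.49 ± 1.80 (CEBPB), -1.57 ± 1.41 (PGR), 1.74 ± 1.13 (HSD11B1) and -0.47 ± 1.06 (IL11). IL15 stood at -2.07 ± 1.10, SST at -1.38 ± 1.98, ACTA2 at 0.47 ± 2.11, TOP2A at 0.30 ± 0.70, CCNB1 at 1.13 ± 0.94, IL6 at 2.95 ± 1.44 and DIO2 at 2.19 ± 0.78. None of them passed.

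Among the 32 gene lists, 3 were higher at 2 h than at 0 h by camera. Genes of cholesterol synthesis and uptake had a mean difference of 0.95 with 17 of 21 measured members higher (adjusted p = 0.0018), and among them INSIG1, which restrains sterol synthesis, stood at 3.49 ± 0.75 and MVD at 2.89 ± 1.36. DNA replication genes had a mean of 0.68 with 27 of 32 higher (adjusted p = 0.0019), with CCNE2 at 2.09 ± 0.83 and CDT1, a licensing factor, lower at -2.48 ± 0.77. Immediate cAMP and CREB target genes had a mean of 0.65 with 20 of 30 higher (adjusted p = 0.020). With an estimated correlation the adjusted p was 0.602 for cholesterol, 0.383 for DNA replication and 0.383 for CREB targets, so no call held, nor did any with fry. With the donor as a block the first 2 lists passed (adjusted p = 0.043 and 0.013) and CREB targets did not (0.145). With the identical column as the 2 h array, the mean of the CREB targets was -0.66. Adjusted over the list alone, INSIG1 passed in its list, STAR (-4.09 ± 0.83) and HSD17B2 (5.27 ± 1.31) among steroid genes, and FGF1 (2.84 ± 0.63) and FGF9 (3.37 ± 0.81) among vascular factors. The other 29 lists did not pass, 16 with a mean above 0 and 13 below.

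Sustained change was asked with 12 to 48 h against 0 h, 8 arrays against 1. RPLP1 stood at 8.0 ± 0.79, DENND2B at 6.89 ± 1.22 and SFI1 at 5.27 ± 0.68, each by 1 probe set that its other probe sets did not follow (-0.21 for RPLP1, 0.92 for DENND2B, 0.95 and 0.33 for SFI1). Lower values were HBB at -6.18 ± 0.99, MAPKAPK3 at -5.26 ± 0.71 (its other probe sets -0.69 and 0.25) and TAB1 at -4.91 ± 0.69. None passed (0 of 12542 in limma, 807 at an unadjusted p under 0.05). With probe sets averaged per gene, 4 of 8210 genes passed. INHBB, the beta B subunit of activin and inhibin, was higher by 4.66 ± 0.50 in this fit. The other 3 were SLC25A24, SYMPK and HBB. The genes always followed did not pass: PRL stood at 2.27 ± 1.35, IGFBP1 at 0.48 ± 0.75, FOXO1 at -0.12 ± 0.53, NR4A1 at 0.89 ± 0.57, CREM at -1.66 ± 0.50, CEBPB at -0.99 ± 1.35, PGR at 1.40 ± 1.06 and HSD11B1 at 1.74 ± 0.85. IL11 stood at 0.58 ± 0.79, IL15 at -1.86 ± 0.82, SST at 0.68 ± 1.48, ACTA2 at -0.71 ± 1.58, TOP2A at -0.31 ± 0.53, CCNB1 at -0.98 ± 0.71, IL6 at 1.11 ± 1.08 and DIO2 at 1.58 ± 0.59.

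Cytokines, chemokines and NF-kB targets were higher at 12 to 48 h than at 0 h as a list, with a mean of 0.71 and 27 of 34 members higher (adjusted p = 0.0027, and 0.336 with an estimated correlation). CXCL3 stood at 2.58 ± 0.60 and CXCL2 at 2.46 ± 0.67. The difference rested on the single 0 h array: 24 to 48 h against 0 h gave a list mean of 0.67, and against 2 h 0.10 (adjusted p = 0.585). Lower lists were actin and contractile genes (mean -0.93, 24 of 28 lower, adjusted p = 0.0098), matrix proteases and inhibitors (-0.79, 21 of 26 lower, 0.0104), oxidative phosphorylation (-0.61, 33 of 38 lower, 0.0104) and protein kinase A components (-0.55, 20 of 28 lower, 0.022). Without the 12 h arrays, both of which had high hybridization controls, oxidative phosphorylation, 12 to 48 h vs 0 h, had a mean of -0.18 (adjusted p = 0.366), protein kinase A pathway components, 12 to 48 h vs 0 h, -0.32 (0.220) and matrix proteases and inhibitors, 12 to 48 h vs 0 h, -0.37 (0.301). The mean of oxidative phosphorylation ran from -0.85 without replicate 1 of 12 h to -0.36 without replicate 2. The members with the smallest p in the 4 lower lists were TPM1 (-2.59 ± 0.70), ADAM9 (-2.06 ± 0.56), NDUFA5 (-2.17 ± 0.86) and RAPGEF3 (-1.68 ± 0.47). With an estimated correlation the adjusted p was 0.639 for actin, 0.432 for proteases, 0.639 for oxidative phosphorylation and 0.408 for protein kinase A components, and no list held with fry. Adjusted over the list alone, INHBB passed, as did COL15A1 (2.94 ± 0.50), DKK1, a WNT antagonist (-4.26 ± 0.57), CCN2 (-3.13 ± 0.68) and GAPDH (2.30 ± 0.50). The GAPDH value is a mean of probe sets, which stood at 4.47 and -1.09 for 24 to 48 h against 0 or 2 h. The blocked fit called 9 lists in place of 5. With 24 to 48 h in place of 12 to 48 h, 3 lists were called: mitosis (-0.72), actin (-0.72) and cytokines (0.67). With an estimated correlation their adjusted p was 0.166, 0.908 and 0.166.

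Each later time was also set against the single 0 h array. INHBB stood 5.74 ± 0.61 above 0 h at 24 h, 6.19 ± 0.61 at 36 h and 5.71 ± 0.61 at 48 h. PRL, which encodes prolactin, a secreted product of decidual cells, stood at 2.68 ± 1.56, 3.60 ± 1.56 and 3.12 ± 1.56 at these times. IGFBP1, another secreted decidual protein, stood at 1.32 ± 0.87, 1.33 ± 0.87 and 1.42 ± 0.87. DIO2, a deiodinase, stood at 1.43 ± 0.68, 1.97 ± 0.68 and 2.74 ± 0.68, and IL11 at 0.22 ± 0.92, 2.07 ± 0.92 and 2.42 ± 0.92. The arrays of the 2 donors differed for some of these, each set against the 0 h array of donor 2. For donor 1 and donor 2, PRL stood at 4.33 and 1.03 at 24 h, 4.95 and 2.25 at 36 h, and 2.27 and 3.97 at 48 h. IL11 stood at 1.13 and -0.69 at 24 h. HBB stood at -7.33, -7.23 and -5.47, and 1 probe set of MAPKAPK3 at -5.20, -4.91 and -5.44, which its other 2 did not follow (-0.24 and -0.19 at 24 h, -1.02 and 0.24 at 36 h, 0.14 and 0.21 at 48 h). GPR183 at 24 h (-5.46 ± 0.75), PCLAF at 36 h (-4.98 ± 1.23) and TAB1 at 48 h (-5.18 ± 0.79) completed the largest lower values. No probe set passed at 24, 36 or 48 h (0 in limma, with 502, 499 and 696 at an unadjusted p under 0.05), nor in the F over all times (0, with 2593). Without replicate 1 of 12 h the F gave 1334 probe sets, and with all 12 columns 490.

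Early genes were also set directly against 12 to 48 h. KRT19 stood 4.97 ± 1.47 higher at 2 h, SULF1 4.96 ± 1.72 and NR4A1 4.74 ± 0.68 (its other probe sets 2.55 and -0.88). DENND2B stood at -10.73, SFI1 at -7.15 and RPLP1 at -7.05, again by single probe sets. None passed (0 in limma, 984 at an unadjusted p under 0.05). Of the lists, 10 were higher at 2 h and 2 lower, led by CREB targets with 25 of 30 higher, a mean of 1.16 and an adjusted p of 8.11e-05 (0.163 with an estimated correlation). None of the 12 held with an estimated correlation, where the smallest adjusted p was 0.163. The calls rest on 1 array at 2 h and count the 12 h arrays among the later ones.

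The largest number of calls in a planned comparison with 0 h came at 12 h, where 58 probe sets rose and 232 fell, and at that time both arrays had high hybridization controls. The passing genes with 1 direction on both arrays numbered 46 risen and 213 fallen. Risen were DENND2B (8.60 ± 1.40), RPLP1 (8.12 ± 0.91), SFI1 (7.69 ± 0.78), the receptor gene GNRHR (6.53 ± 1.08) and TPTEP1 (5.89 ± 0.88). DENND2B, RPLP1 and SFI1 had other probe sets that did not pass (0.28, -2.06, 0.70 and 0.64). Fallen were the transporter gene SLC16A4 (-7.83 ± 0.97), ATP13A3 (-6.75 ± 0.81), TM4SF1 (-6.61 ± 1.17; its other probe set -4.74), RHOQ (-6.60 ± 1.01; its other probe set -2.13) and CD164 (-6.58 ± 0.82). CREM, a cAMP-responsive transcription factor gene, fell by 3.51 ± 0.58 over 3 probe sets (adjusted p = 0.0287). As log2 ratios it stood at -2.06 and -2.62 at 12 h, -2.35 in the identical column and 1.17 on the 0 h array. The identical column has high hybridization controls too, but so has the 48 h array of donor 2, where CREM stood at 0.086. Of the lists, 14 were lower and 4 higher; collagens and matrix (-1.94, 39 of 47 lower), oxidative phosphorylation (-1.90, 35 of 38) and ribosomal proteins (-1.91, 29 of 32) fell beside the housekeeping genes (-1.91, 10 of 12), and leukocyte markers were higher (0.92, 20 of 24). With an estimated correlation these lists had adjusted p of 0.435, 0.494, 0.622, 0.494 and 0.247. The calls numbered 290 in the main fit, 0 with the donor as a block, 0 after quantile normalization and 0 with the hybridization controls as a covariate. Without replicate 1 of 12 h they numbered 2701. The median of all probe sets at 12 h lay 0.117 above 0 h, and -0.006 after quantile normalization.

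The comparison of 48 h with 12 h gave the counterpart, 446 probe sets higher at 48 h and 58 lower. PDE4B, a phosphodiesterase that breaks down cAMP, was higher by 7.32 ± 0.58, the matrix protease MMP10 by 7.26 ± 1.07, MLLT11 by 6.54 ± 0.83, LRIG1 by 6.0 ± 0.70 (its other probe set 0.28) and MORF4L2 by 5.64 ± 1.20. Lower were GNRHR (-5.50 ± 0.89), TPTEP1 (-5.43 ± 0.72), the proliferation marker MKI67 (-4.70 ± 0.79; its other probe set -3.46), CPA1 (-4.58 ± 0.63) and MSX2 (-4.49 ± 0.96), whose other probe set stood at 1.02. The hybridization controls moved with this contrast too. The calls numbered 504 in the main fit, 0 with the donor as a block, 0 after quantile normalization, 0 without replicate 1 of 48 h, 23 without replicate 2 of 48 h and 2639 without replicate 1 of 12 h.

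The later state was described by 24 to 48 h against 0 or 2 h, a comparison devised after the data were examined, with 6 arrays against 3. The 3 include the identical column, assumed to be a 0 h or a 2 h array. INHBB (chromosome 2, 120346136 to 120351803 on GRCh38) rose 48.0-fold, by 5.58 ± 0.35 on the log2 scale, and stood between 0.93 and 1.83 on the 6 later arrays against -4.86 to -3.47 on the 3 early ones. Higher too were the chemokine receptor CXCR4 by 4.82 ± 0.78, the nucleotide sugar receptor P2RY14 by 4.54 ± 0.70, the coagulation factor subunit F13A1 by 4.11 ± 0.45 and COL15A1, a collagen of basement membrane zones, by 3.88 ± 0.35 (14.7-fold). DEPP1 rose by 4.78 ± 0.36, ABCA8 by 4.0 ± 0.63, ATRNL1 by 3.50 ± 0.39, ATP8A1 by 3.44 ± 0.59 (its other probe set 1.85) and ENPP2, which makes lysophosphatidic acid, by 3.35 ± 0.49 (its others 1.20 and 0.98). CDKN1C, an inhibitor of the cell cycle, rose by all 3 of its probe sets (2.75, 2.11 and 2.84). ADCY1 (3.72 ± 0.48) and GAPDH (4.47 ± 0.30) rose by 1 probe set each, and their other probe sets stood at -0.24 and -1.09.

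The 12 fallen genes with the largest changes are given here. KRT18 (chromosome 12, 52948855 to 52952906) fell by 3.37 ± 0.42 on the log2 scale, as did the tropomyosins TPM2 (-3.18 ± 0.45) and TPM1 (-2.45 ± 0.37) and the Rho and CDC42 regulators ARHGDIB (-2.51 ± 0.35) and CDC42EP2 (-2.58 ± 0.32). The surface proteins CD9 (-2.60 ± 0.31), ADGRG6 (-2.32 ± 0.32) and CD44 (-2.23 ± 0.32), the binding protein IGFBP5 (-3.17 ± 0.45), PRSS2 (-3.22 ± 0.41), SP110 (-3.01 ± 0.41) and MTCL1 (-2.15 ± 0.27) also fell. Of the other 5 probe sets of IGFBP5, 1 stood at 0.74 and the rest between -0.85 and -3.93; all other probe sets of CD44, TPM1 and TPM2 had the direction of the named one.

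In all, 46 probe sets passed, 28 higher and 18 lower, and 43 of them named 40 genes (1386 probe sets at an unadjusted p under 0.05). In none of the 46 did the arms overlap, which held for 819 of 12542 probe sets, while chance gives a share of 2.38%. Without the identical column 26 passed, 18 of them among the 46. With the donor as a block as well 6 passed, 5 of them among the 46. Left out singly, the 2 h array gave 16, replicate 1 of 24 h, replicate 2 of 36 h and replicate 1 of 48 h gave 25 each, and replicate 1 of 36 h gave 27. Without arrays that had high hybridization controls 9 passed, 7 of them among the 46, but all 46 kept their direction on these 7 arrays and a median of 95.0% of their log2 difference (75.0% to 120.2%). The 46 were picked on arrays that include these 7, and without overlap between the arms their direction could not change. With the 12 h arrays added to the later arm 4 passed.

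**Figure D2:**
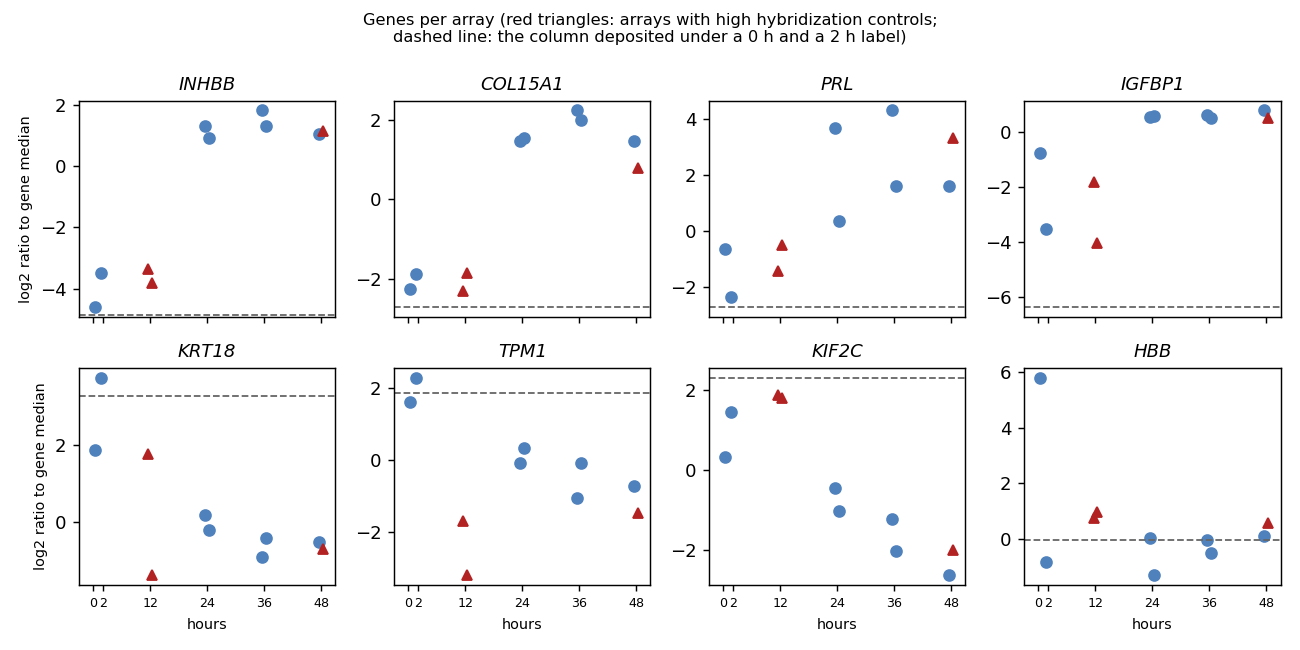
Log2 ratio of 8 genes to their median (vertical) against hours (horizontal), 1 point per array, shifted slightly apart by donor; the dashed line is the column deposited under a 0 h and a 2 h label, and red triangles are arrays with high hybridization controls. INHBB lies between 0.93 and 1.83 at 24 to 48 h and between -4.86 and -3.37 before; HBB is high (5.78) on the 0 h array.

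Markers of decidualization were higher in this comparison as a list, with a mean of 0.91 and 16 of 24 members higher (adjusted p = 0.0176, and 0.578 with an estimated correlation). PRL stood at 4.39 ± 0.85 (21.0-fold), SST, which encodes somatostatin, at 4.73 ± 1.27, IGFBP1 at 4.15 ± 0.91 (17.8-fold), BMP2 at 1.80 ± 0.47 and the transcription factor gene FOXO1 at 1.78 ± 0.46. Without the identical column, in which SST and IGFBP1 were lowest, SST stood at 2.47 ± 0.39 (5.55-fold, adjusted p = 0.0398), IGFBP1 at 2.74 ± 0.58 (6.70-fold), PRL at 3.99 ± 1.0 (15.9-fold) and FOXO1 at 1.16 ± 0.37. With that column none of these passed over all genes (PRL had an adjusted p of 0.0554, IGFBP1 0.0832), and 10 of the 24 passed when adjusted over the list alone. CRYAB (-1.62 ± 0.35) and CNR1 (-1.38 ± 0.41) stood lower. Against the 0 h array alone, 24 to 48 h gave a list mean of 0.17, with 14 of 24 members higher. In that comparison PRL stood at 3.13 ± 1.37, SST at 1.78 ± 1.51, IGFBP1 at 1.36 ± 0.76 and FOXO1 at 0.62 ± 0.54. The call was lost without replicate 1 of 48 h (decidualization markers, 24 to 48 h vs 0 or 2 h, adjusted p = 0.0511) and without the identical column alone (mean 0.32, adjusted p = 0.384), with the same mean when the donor was a block as well (0.376). Without arrays that had high hybridization controls, that column among them, the mean was 0.35 (0.249). Of the remaining genes always followed, IL11 stood at 2.88 ± 0.88 (1.81 without the identical column), DIO2 at 2.02 ± 0.78 (0.95 without it), HSD11B1 at 1.01 ± 0.79, PGR at 0.62 ± 0.81 (1.39 without it), CREM at 0.39 ± 0.63, IL6 at 0.29 ± 0.82, CEBPB at 0.24 ± 0.32, NR4A1 at -0.29 ± 0.57, IL15 at -0.38 ± 0.66, TOP2A at -0.73 ± 0.38, CCNB1 at -1.58 ± 0.46 and ACTA2 at -1.59 ± 0.79.

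Genes of mitosis and G2/M were lower at 24 to 48 h, with 30 of 34 members lower and a mean of -1.18 (adjusted p = 2.51e-10, and 0.278 with an estimated correlation). KIF2C, a mitotic kinesin, fell by 2.92 ± 0.54 with an adjusted p of 0.0465 over all genes. CDKN3 (-2.97 ± 0.75), FOXM1 (-2.44 ± 0.58) and CDC20 (-2.37 ± 0.59) were among the 13 that passed when adjusted over the list alone. Actin and contractile genes were lower in 21 of 28 (mean -0.88, adjusted p = 6.10e-07, and 0.326 with an estimated correlation), 11 of them past the test adjusted over the list alone, with CNN1 at -3.46 ± 0.81 and MYLK at -2.21 ± 0.53. Cholesterol synthesis and uptake was lower in 18 of 21 (mean -0.75, adjusted p = 1.91e-06, and 0.326 with an estimated correlation), with FDPS at -1.08 ± 0.33 and DHCR7 at -1.04 ± 0.32 among 6 that passed adjusted over the list alone. Against the 2 h array alone the cholesterol list had a mean of -1.11 (adjusted p = 1.68e-05, and 0.438 with an estimated correlation), and against the 0 h array alone -0.16 (0.661). SRF and YAP targets were lower in 12 of 14 (mean -0.51, adjusted p = 0.0149, and 0.326 with an estimated correlation), among them CRIM1 (-1.99 ± 0.28) and CCN1 (-2.21 ± 0.54), while TGFB2 stood at 2.08 ± 0.47. Without the 2 h array the mean of the SRF and YAP target genes, 24 to 48 h vs 0 or 2 h, was -0.26 (adjusted p = 0.0875). Blocked by donor without the identical column, these 4 lists kept an adjusted p of 1.77e-06, 5.07e-06, 0.000508 and 0.00159. No list passed with fry, whose adjusted p was 0.057 for mitosis and actin.

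The insulin-like growth factor system was higher in 13 of 17 (mean 0.73, camera adjusted p = 0.0065, and 0.326 with an estimated correlation). Against the 0 h array alone the mean of this list was 0.36. Without the identical column it was 0.52. Of the 5 members that passed adjusted over the list alone, IGFBP1, which is also in the decidualization list, stood at 4.15 ± 0.91. Higher too were PAPPA (1.86 ± 0.43), a protease that cleaves binding proteins, IGFBP3 (1.70 ± 0.48) and IGFBP4 (1.088 ± 0.31), while IGFBP5 went the other way. Cytokines were higher in 25 of 34 (mean 0.46, adjusted p = 0.0176, and 0.326 with an estimated correlation), with 0 past the test adjusted over the list alone, and the TGF-beta, BMP and activin pathway in 23 of 34 (mean 0.43, adjusted p = 0.0427, and 0.591 with an estimated correlation). In the latter, BMP4 stood at 1.31 ± 0.37 and SMAD3 at -1.32 ± 0.27. Oxidative phosphorylation had a mean of -0.19 with 30 of 38 lower (adjusted p = 0.0471, and 0.614 with an estimated correlation). With 1 array other than the identical column left out, the mean for oxidative phosphorylation, 24 to 48 h vs 0 or 2 h, ran from -0.31 (without the 2 h array) to -0.14 (without replicate 1 of 48 h). Without the identical column it was -0.065 (adjusted p = 0.480), and that of the TGF-beta pathway 0.22 (0.564). With 1 of the other 8 arrays left out the call was lost in 5 fits for oxidative phosphorylation, in 3 for the TGF-beta pathway and in 2 for cytokines. Blocked by donor without the identical column, the adjusted p was 0.036 for the insulin-like growth factor system, 0.053 for cytokines and 0.488 for the other pair of lists.

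The other 23 lists did not pass in this fit. Without the identical column 5 of them had the other sign: CREB targets (-0.46), collagens and matrix (-0.076), proteases (-0.14), steroid genes (0.028) and ribosomal proteins (0.33). Others moved and kept their sign, among them endoplasmic reticulum stress (0.35 to 0.017), cell cycle inhibitors (0.32 to 0.095) and protein kinase A components (-0.0062 to -0.24). Vascular factors passed by camera without that column (mean -0.62, adjusted p = 0.0031). With the donor as a block as well, 3 of the 23 passed: vascular factors (adjusted p = 0.0028), CREB targets (0.0496) and ribosomal proteins (0.0496). Without the block CREB targets and ribosomal proteins each had an adjusted p of 0.0513. Against the 2 h array alone, CREB targets had a mean of -0.78 (adjusted p = 0.00058, and 0.304 with an estimated correlation), and against the 0 h array alone -0.14 (0.757). Means above 0 were those of endothelial markers (0.48), neuronal genes (0.40), endoplasmic reticulum stress (0.35), cell cycle inhibitors (0.32), cAMP and CREB targets (0.30, which rested on the identical column), WNT (0.18), proteases (0.17), leukocyte markers (0.14), collagens and matrix (0.12), housekeeping genes (0.10) and stromal fibroblast markers (0.026). Means below 0 were those of protein kinase A components (-0.0062), steroid genes (-0.020), oxidative stress (-0.027), ribosomal proteins (-0.067), epithelial markers (-0.20), metallothioneins (-0.21), heat shock (-0.23), DNA replication (-0.25), glycolysis (-0.28), interferon-stimulated genes (-0.29), vascular factors (-0.31) and pericyte markers (-0.55). Median and mean differed in sign for collagens, housekeeping, stromal fibroblast, protein kinase A, steroid, heat shock and epithelial lists. Epithelial markers moved apart, with KRT18 and KRT19 (-3.75 ± 0.69) lower and CD24 (2.76 ± 0.46) higher.

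**Figure D3:**
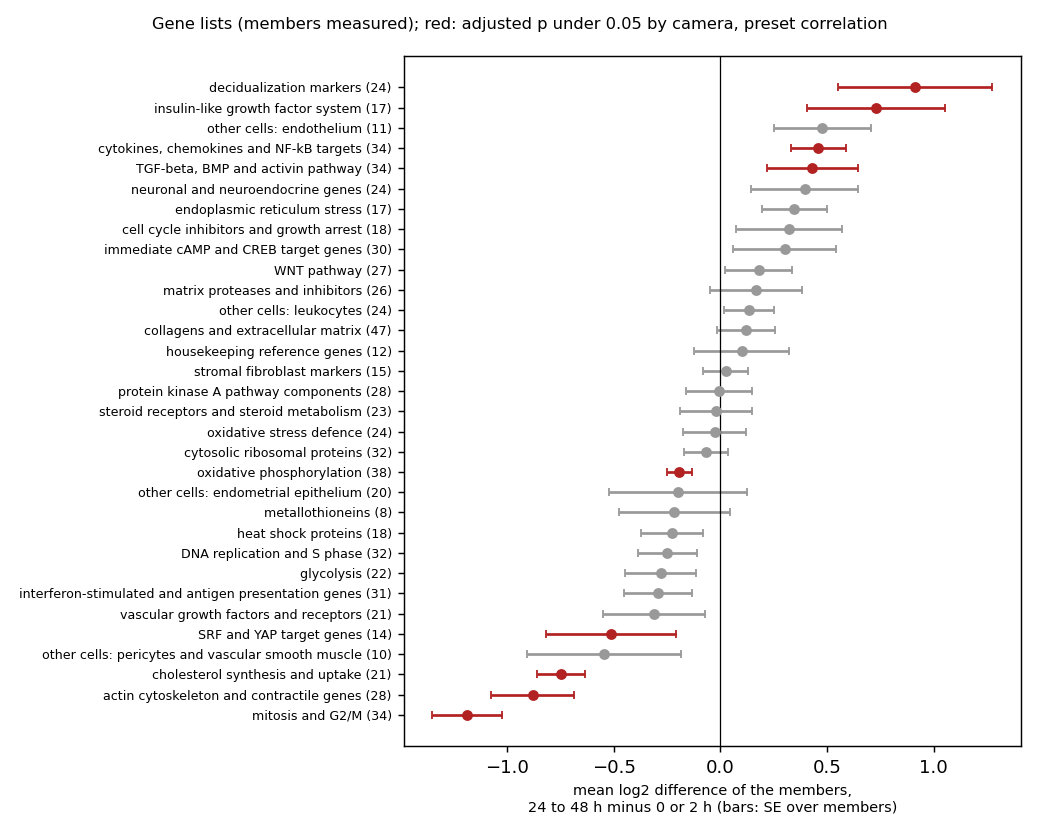
Mean log2 difference of each list's measured members between 24 to 48 h and 0 or 2 h (points) with the standard error over members (bars); red marks the 9 lists with an adjusted p under 0.05 by camera with a preset correlation. Mitosis (-1.18), actin (-0.88) and cholesterol (-0.75) lie lowest among these and decidualization markers (0.91) highest.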

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

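The tests on hybridization controls, on the identical column and on the added comparisons were chosen after the data were examined, and the count of splits after the result it tests had been seen; quantile normalization was planned. The hybridization control probe sets, which no comparison uses, stood far above the other arrays on 4 distinct columns: at a median log2 ratio of 1.36 in the identical column, under both its labels, at 1.68 and 3.60 on the 12 h arrays and at 1.38 on the 48 h array of donor 2. The identical column, also outside the planned comparisons, was at least 2-fold lower than both the 0 h and the 2 h array in 1441 of 12542 probe sets, and at least 2-fold higher than both in 1154.

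The calls at 12 h against 0 h may stem from lower array quality at 12 h. If so, the probe sets that fell at 12 h should also be low on the 48 h array with high controls. Against the other 48 h array, less the donors' difference at 24 and 36 h, the fallen probe sets had a median of -0.57 ± 0.070 with 78.9% lower, while the risen ones had 0.19 and all probe sets 0.077. The error here is over the probe sets, with 1 array against 1 at 48 h. A response to 12 h of cAMP cannot be told apart from it. With the controls as a covariate 0 of 290 calls are left, which decides nothing, because both 12 h arrays have high controls and the covariate goes with that time.

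The mitosis list had a mean difference of -0.58 between 36 h and 24 h, in arrays without high controls. After quantile normalization its mean was -0.76. In the donor with the smaller shift it was -0.48 ± 0.20 (standard error over the members) with 22 members lower, and -0.68 with 26 lower in the other. The mean after quantile normalization argues against scaling between arrays as the whole cause. The donors' means met the condition set beforehand against a single donor as the cause. Each donor gives 1 array against 1, however, and the error is over members that can be correlated. The list was also singled out on these same arrays, so the donors' means do not decide this. With the hybridization controls as a covariate the mean was -0.54 (adjusted p = 0.000377 by camera). Those controls differed little here (-0.27 and -0.38 at 24 h, -0.45 and -0.92 at 36 h). The covariate could thus hardly move this mean, and it does not decide on array quality. The shift predicted from the pair of 48 h arrays was -0.094 ± 0.053 (error over the members). At that size it met the condition set beforehand against array quality, but it rests on 1 library and was left undecided. With an estimated correlation the list did not pass (adjusted p = 0.148). A slowing of division with longer exposure or with time in culture is a hypothesis that no array separates.

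The comparison of 24 to 48 h with 0 or 2 h gave 46 probe sets. Of the 84 splits of the 9 arrays into 3 and 6, 1 gave as many, the real one, and the highest other split gave 4 (13 other splits gave any). A random split of these arrays thus rarely gave as many. The grouping itself was devised after the data were examined, so chance in that choice cannot be excluded. With the hybridization controls as a covariate 78.3% of the calls (36 of 46) were kept, which met the condition set beforehand against array quality as the whole cause. These controls were high in both arms, at 1.36 in the identical column and 1.38 on the 48 h array of donor 2. They thus do not separate the arms, and the covariate could hardly take up the difference. It does not decide on array quality. On the 7 arrays without high controls 9 probe sets passed, and the 46 kept a median of 95.0% of their log2 difference. The 46 were picked on arrays that include those 7, so the size kept is no separate evidence. Time in culture could account for the changes as well as cAMP, and these cannot be told apart, because 0 arrays are labelled as kept for 24 to 48 h without cAMP.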

How the results depend on the processing

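Quantile normalization, the pseudocount, the intensity trend with a robust prior, the donor as a block, only the groups compared and each array left out in turn were chosen before the data were examined, as were the estimated correlation, fry and the choice of probe set for the lists of 2 h and of 12 to 48 h against 0 h. The fit on all 12 columns is the one first designed, and was set beside the others once the identical columns had been found. The other settings, and the comparisons of 24 to 48 h with 0 or 2 h and of 36 h with 24 h, were chosen after the data were examined. The floors, the filters on dim probe sets and the count of 2-fold changes in both donors were not run, since ratios carry no level.

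The change over time had 0 probe sets, 0 to 1334 with 1 array left out (1334 without replicate 1 of 12 h), 490 with all 12 columns, 178 and 213 with the identical column as a 0 h or a 2 h array, and 141 with probe sets averaged per gene. The 290 probe sets of 12 h against 0 h became 0 with quantile normalization, the intensity trend, the donor as a block, only the groups compared, the hybridization controls as a covariate or array weights, and 3 with the pseudocount. They became 382 to 2701 with 1 array left out (2701 without replicate 1 of 12 h), 1473 with all 12 columns and 1189 with the identical column as a 0 h array.

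For 24 h against 0 h the 0 became 3 with the pseudocount, 1 with all 12 columns, 1 with the identical column as a 0 h array and 7 with array weights. For 36 h against 0 h it became 2 with all 12 columns, 2 with the identical column as a 0 h array and 7 with array weights. For 48 h against 0 h it became 4 with the pseudocount, 1 with all 12 columns and 1 with the identical column as a 0 h array. For 12 to 48 h against 0 h it became 3 with quantile normalization, 9 with the pseudocount, 4 with all 12 columns, 2 with the identical column as a 0 h array, 7 with array weights and 4 with probe sets averaged per gene. For 2 h against 12 to 48 h it became 8 with the pseudocount, 0 to 1 with 1 array left out (1 without replicate 1 or replicate 2 of 48 h), 3 with all 12 columns, 3 with the identical column as a 2 h array and 4 with array weights.

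The 504 probe sets of 48 h against 12 h became 0 with quantile normalization, the intensity trend, the donor as a block, only the groups compared, the hybridization controls as a covariate or array weights, 4 with the pseudocount and 846 with all 12 columns. With 1 array left out they ran from 0 (without replicate 1 of 48 h) to 2639 (without replicate 1 of 12 h), with 23 without replicate 2 of 48 h.

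Of the gene lists, the 3 of 2 h against 0 h became 9 with the donor as a block, 7 and 5 with the identical column as a 0 h or a 2 h array, and 0 with an estimated correlation or fry. The 5 of 12 to 48 h against 0 h became 9 with the donor as a block, 5 to 10 with 1 array left out, 10 with all 12 columns, 11 and 9 with the identical column as a 0 h or a 2 h array, 3 with 24 to 48 h in place of 12 to 48 h, and 0 with an estimated correlation or fry. The 2 of 36 h against 24 h became 1 to 2 with 1 array left out, 1 with the probe set of highest mean, and 0 with an estimated correlation or fry.

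The 46 probe sets of 24 to 48 h against 0 or 2 h became 98 with the pseudocount, 30 with the intensity trend, 26 without the identical column, 6 without it and with the donor as a block, 16 to 41 with 1 other array left out (16 without the 2 h array), 4 with the 12 h arrays, 9 without arrays with high hybridization controls and 73 with array weights. Of the 46 themselves, 18 were still called without the identical column and 5 with the block as well. The 9 lists became 6 without the identical column, 5 to 11 with 1 other array left out (5 without replicate 1 of 48 h), 14 with the 12 h arrays, and 0 with an estimated correlation or fry. Of the 6, 1 (vascular factors) was not among the 9.

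Among the values followed over all settings, which leave out lists that were not called, signs changed for genes that passed in no such comparison and for 1 list. Of the 23 lists not called for 24 to 48 h against 0 or 2 h, 5 had the other sign without the identical column. For 2 h against 0 h, CEBPB was at -0.61 and ACTA2 at -0.14 with the donor as a block. With the identical column as a 0 h array IGFBP1 was at 0.031, FOXO1 at 0.11, CREM at 0.97, IL11 at 1.26, SST at 2.36 and ACTA2 at -0.12. As a 2 h array it put CEBPB at -0.17 and the CREB target list at -0.66. For 12 to 48 h against 0 h, FOXO1 was at 0.27 with quantile normalization, 0.072 with the pseudocount, 1.08 with all 12 columns or the identical column as a 0 h array, and 0.46 without arrays with high hybridization controls. CREM was at 0.098 with all 12 columns or the identical column as a 0 h array, CEBPB at 0.14 without arrays with high hybridization controls, and ACTA2 at 0.49 with the covariate.

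For 24 to 48 h against 0 or 2 h, CREM was at -0.65, CEBPB at -0.12 and IL6 at -0.29 without the identical column, blocked or not. With 1 of the other arrays left out IL15 ran from -0.78 to 0.26, IL6 from -0.16 to 1.31, NR4A1 from -0.93 to 0.59 and PGR from -0.15 to 0.85, while PGR was at 1.39 without the identical column. With the 12 h arrays CREM was at -0.22 and CEBPB at -0.87. Without arrays with high hybridization controls CREM was at -0.64, CEBPB at -0.082 and IL6 at -0.43. CREM was at -0.047 with the covariate and -0.27 with array weights, and IL15 at 0.053 without replicate 2 of 48 h.

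Each value was counted once per gene or list, comparison and setting. For named genes 913 of these values kept their result, 331 were weaker and 26 stronger. For lists 205 kept it, 90 were weaker and 1 had the other sign. For the genes always followed 742 kept it, 6 were stronger and 36 had the other sign.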

Other observations

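Between 24 h and 36 h, a comparison added after the data were examined, genes of mitosis and G2/M were lower by camera, with 25 of 34 members lower, a mean of -0.58 and an adjusted p of 2.23e-05 (0.148 with an estimated correlation). CDKN3, a phosphatase of cyclin-dependent kinases, stood at -2.87 ± 0.66, the kinesin KIF11 at -1.86 ± 0.79, TOP2A at -1.28 ± 0.50 and the checkpoint kinase BUB1 at 1.95 ± 0.76; none passed adjusted over the list alone. Actin and contractile genes were lower in 24 of 28, with a mean of -0.49 and an adjusted p of 0.0316 (0.953 with an estimated correlation), among them ACTG2 at -2.38 ± 1.14 and TAGLN at -1.66 ± 1.15. The mean of the actin cytoskeleton and contractile genes, 36 h vs 24 h, ran from -0.70 (without replicate 2 of 36 h) to -0.29 (without replicate 1 of 36 h). The actin list was not called without replicate 2 of 24 h (adjusted p = 0.688) or without replicate 1 of 36 h (0.430), which left mitosis alone. No probe set passed (0 in limma, with 302 at an unadjusted p under 0.05). HSD11B1, which forms active cortisol, stood at 2.30 ± 0.80 and IL11 at 1.85 ± 0.75.

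In the identical column PRL stood at -2.72, IGFBP1 at -6.39, INHBB at -4.86, KRT18 at 3.26 and KIF2C at 2.31, each as a log2 ratio to the gene's median. The 0 h array of donor 2 had -0.65 for PRL, -0.78 for IGFBP1, -4.61 for INHBB, 1.85 for KRT18 and 0.34 for KIF2C. The 2 h array of donor 1 had -2.36 for PRL, -3.55 for IGFBP1, -3.47 for INHBB, 3.73 for KRT18 and 1.45 for KIF2C. On the 12 h arrays INHBB stood at -3.37 and -3.83 and COL15A1 at -2.31 and -1.86.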
